A study of Mus musculus with 10 samples.

How the data were processed

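Gene expression was measured by RNA sequencing in 10 libraries of the mouse macrophage line Ana-1, made from cells sorted for transduction 48 h after infection with a hairpin. Total RNA was extracted with Trizol and standard Illumina libraries were made, per the labels' protocols. The libraries fall into shRen (4), sh15-LOX-2.1252 (sh1252 here, 3) and sh15-LOX-2.2865 (sh2865, 3), and the columns of the table were tied to groups by their names, which show the group but not which sample of it. Per the submitters' processing notes STAR 2.6.0 and the build GRCm38 were used, and their roles, the read counter and the annotation are not given in the sources used here.

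The deposited table is named for TPM, but the values the authors deposited are RPKM up to a constant: each column sums to between 55307 and 56558, and each value is a whole number of reads divided by transcript length and by the library's depth (1 deposited unit is 8.376 RPKM). Whole reads were recovered from these steps for 15377 of the 15377 genes above 0 in at least 2 libraries, 100.0% of their values being whole within a tolerance of 1e-09, with the constant fixed by 726 single-exon genes. A count of 0 allows up to 3 reads, for counting error only. Since the design had assumed TPM, each library was rescaled to a sum of 1000000, which turns these RPKM values into TPM.

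Of 24421 entries, 27 whose names had been turned into calendar dates were left out (0.129% of the values), and 24394 were used. A match to RefSeq symbols or synonyms was found for 24274, and coordinates are on GRCm38. Genes at 1 TPM or more in at least 3 libraries (11534) were tested on log2(TPM + 1), with a pseudocount of 1, by limma 3.58.1 (R 4.3.3) with empirical Bayes moderation and a mean-variance trend. A model with 3 groups gave 4 comparisons: the mean of both hairpins against shRen, each hairpin against shRen, and sh1252 against sh2865. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and a gene was counted as shared when it passed with each hairpin in the same direction. Alox8, below the filter, was tested by an exact permutation test.

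Gene lists were 33 sets of 985 genes, 965 of them in the table, written down in advance. The 27 with at least 5 tested members were tested by camera with a preset correlation of 0.01 between members, and again with an estimated correlation, adjusted over the 27 lists of each comparison. The comparisons, tests, gene lists, naming rule and most alternatives were set before the data were examined. By the naming rule, Alox8, Alox15, Alox5, Alox12, Arg1, Mrc1, Nos2, Tnf, Il1b, Ccl2, Cd36, Abca1 and Abcg1 were named in any case. For both hairpins the rule took the 10 genes that rose and the 10 that fell most among those past the threshold with a mean of at least 5 TPM, the same sign with each hairpin and all 6 knockdown libraries beyond all 4 shRen libraries, leaving out predicted genes and pseudogenes. It took 5 in each direction for the other comparisons, up to 4 members with the smallest adjusted p of each list that passed, and up to 3 of any other list described.

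Comparisons against the same controls share their chance values, so 100 sets of unchanged libraries were simulated, with simulated controls common to both hairpins. The real controls were also split. Heptamers in 3′ UTRs of at least 50 nt were scored in 10276 of the tested genes (89.1%) by the moderated statistics of genes with and without them, adjusted for length and composition. This search was made after the fold changes were seen, and hairpin sequences are not given in the labels. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for preparation, heptamers and plots.

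Each step was tested on simulated data. For both hairpins, the limma step recovered 97% of genes changed by 1 and 82% of those changed by 0.5 (log2) among 11407 genes with 200 changed, and 5.79% of its calls were false. The figures were 93%, 76% and 2.87% for sh1252 (11417 genes), 95%, 77% and 4.44% for sh2865 (11420 genes), and 94%, 72% and 2.92% for sh1252 against sh2865 (11423 genes). Camera called the list shifted by 0.2 and 0 of the other 26 for both hairpins, but false calls from correlated members were not tested. A heptamer whose genes were shifted for sh1252 ranked 1 in a search of 10276 genes. Alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, median-of-ratios and quantile scaling, limma without trend, with robust moderation and with array weights, fits of the compared groups only, knockdown libraries as 1 group, an exact rank-sum test, an estimated correlation, split controls and leaving out each library. Chosen after the data were seen were the deposited scale, voom on the recovered reads, a block on the numbers of the columns, and leaving out genes with a heptamer tied to a hairpin or without a searched 3′ UTR.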

Results

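RNA was sequenced from Ana-1 cells sorted 48 h after infection with a virus carrying a short hairpin RNA. The control hairpin, shRen, was present in 4 libraries, and hairpins sh1252 and sh2865, both directed against 15-LOX-2 (gene Alox8), in 3 libraries each. The question was which transcripts change when a macrophage line lacks this lipoxygenase. Depth, recovered from the steps in the deposited values, was 23335234, 17081950, 18949642 and 18001645 reads in shRen, 21643022, 18447303 and 16422398 with sh1252, and 22641001, 19476568 and 21899415 with sh2865. The shRen libraries are called ANR-1 to ANR-4 here, those of sh1252 AN12-1 to AN12-3, and those of sh2865 AN28-1 to AN28-3. Between 13919 and 14498 genes were above 0 in a library, and 11534 were tested. Across genes, which are not independent replicates, the correlation of log2 values was 0.989 to 0.994 within groups (12 pairs of libraries) and 0.981 to 0.990 between groups (33 pairs). The leading principal component (32.3% of the variance) set sh1252 apart, and the next (18.2%) set sh2865 apart from shRen. A further component (10.7%) set ANR-4 and AN12-3 against ANR-1, across groups. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Levels are given in TPM as mean ± SD over 4 libraries in shRen and 3 for each hairpin, and fold changes are on the scale of log2(TPM + 1), which understates changes of weakly expressed genes.

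The targeted gene Alox8 (15-LOX-2, GRCm38 chromosome 11: 69183885 to 69197843) encodes a lipoxygenase, an enzyme that adds oxygen to polyunsaturated fatty acids such as arachidonic acid. Its transcript was almost undetected in this line with or without a hairpin, so whether the hairpins lowered it was not detectable at this depth. A single read was found in AN12-1 (0.0304 TPM), and the other 9 libraries, the 4 shRen libraries included, had 0. A count of 0 allows up to 3 reads, which are worth 0.0862 to 0.121 TPM depending on the library, for counting error only. The mean was 0.00506 ± 0.0124 TPM in the 6 knockdown libraries against 0 in the 4 shRen libraries (exact two-sided permutation test, p = 1). Statements on lost 15-LOX-2 therefore rest on the labels, and every difference described here is one between libraries labelled with different hairpins. Among the other lipoxygenases, Alox15 was at 0.181 ± 0.129 TPM in shRen, 0.201 ± 0.202 TPM with sh1252 and 0.149 ± 0.116 TPM with sh2865, too low to be tested. Platelet-type Alox12 was at 0.0970 ± 0.0773 TPM in shRen, 0.0289 ± 0.0501 TPM with sh1252 and 0.112 ± 0.0425 TPM with sh2865, also below the level for testing. Alox5, which starts the synthesis of leukotrienes, was the lipoxygenase with a clear level, and it fell: 7.78 ± 1.06 TPM in shRen, 4.97 ± 0.771 TPM with sh1252 and 4.02 ± 0.521 TPM with sh2865 (log2 fold change -0.68, limma adjusted p = 0.00127), lower in all 6 knockdown libraries than in any shRen library.

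Both hairpins were compared with shRen. The largest rises included receptors of monocytes and macrophages (Ccr2, Cx3cr1 and Clec7a), and the largest falls were a mixed set with Alox5. Camera called lists of metabolic genes (glycolysis, fatty acid and cholesterol synthesis) lower and chemokine, phagocytic and inflammatory lists higher with the preset correlation, and 0 of 27 lists with an estimated one (7 at an unadjusted p under 0.05, lowest adjusted p = 0.129). Limma passed 2209 of 11534 genes at an adjusted p under 0.05, of which 1179 rose and 1030 fell (980 and 1129 with quantile normalization), with 3830 at an unadjusted p under 0.05. Most changes were small: the median size among these genes was 0.25 on the log2 scale, and 15 genes changed at least 2-fold. In 1102 genes the 6 knockdown libraries did not overlap the 4 shRen libraries (596 above and 506 below), a separation that chance gives to 0.952% of genes, and 1006 genes were both changed and separated.

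Ccr2 (GRCm38 chromosome 9: 124101918 to 124109140), the receptor through which the chemokine CCL2 draws monocytes into tissue, rose most of the genes with a mean of at least 5 TPM: 1.19 ± 0.763 TPM in shRen, 8.88 ± 2.49 TPM with sh1252 and 13.5 ± 3.27 TPM with sh2865 (log2 fold change 2.48, limma adjusted p = 7.82e-05). Cx3cr1 (chromosome 9: 120048683 to 120068296), the fractalkine receptor of monocytes and resident macrophages, was at 4.56 ± 1.01 TPM in shRen, 17.8 ± 1.10 TPM with sh1252 and 13.3 ± 2.14 TPM with sh2865 (log2 fold change 1.57, limma adjusted p = 4.25e-05). Atp2b4 (chromosome 1: 133702674 to 133801059), a calcium pump of the plasma membrane, was at 1.79 ± 0.342 TPM in shRen, 5.85 ± 0.793 TPM with sh1252 and 9.70 ± 0.565 TPM with sh2865 (log2 fold change 1.62, limma adjusted p = 6.53e-06). Clec7a (chromosome 6: 129461591 to 129472785), the receptor for fungal beta-glucan, was at 11.7 ± 1.15 TPM in shRen, 30.8 ± 2.97 TPM with sh1252 and 33.9 ± 0.757 TPM with sh2865 (log2 fold change 1.40, limma adjusted p = 2.35e-06). Fabp7 (chromosome 10: 57784923 to 57788450), a carrier of fatty acids in the cytosol, was at 6.62 ± 1.05 TPM in shRen, 10.9 ± 1.42 TPM with sh1252 and 22.5 ± 1.39 TPM with sh2865 (log2 fold change 1.14, limma adjusted p = 7.97e-05). The other named genes that rose were Sema4a (0.94), a semaphorin that acts on T cells; Fut7 (0.92), which builds selectin ligands; the chemokine Ccl6 (0.90); Ccr5 (0.88), a receptor for inflammatory chemokines; and Socs3 (0.84), a brake on cytokine signalling. Their limma adjusted p ran from 0.000105 for Fut7 to 0.0318 for Socs3.

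Among the falls, Cpe (chromosome 8: 64592542 to 64693109), a carboxypeptidase that trims peptide hormones, was at 29.6 ± 0.652 TPM in shRen, 15.4 ± 1.54 TPM with sh1252 and 16.9 ± 1.87 TPM with sh2865 (log2 fold change -0.84, limma adjusted p = 7.82e-05). Angptl2 (chromosome 2: 33215951 to 33247725), a secreted protein linked to inflammation, was at 129 ± 12.9 TPM in shRen, 64.2 ± 7.69 TPM with sh1252 and 87.8 ± 1.05 TPM with sh2865 (log2 fold change -0.78, limma adjusted p = 9.05e-05). Card11 (chromosome 5: 140872999 to 141000596), a scaffold that carries antigen receptor signals to NF-kB, was at 57.2 ± 8.07 TPM in shRen, 27.8 ± 4.46 TPM with sh1252 and 41.7 ± 1.22 TPM with sh2865 (log2 fold change -0.73, limma adjusted p = 0.000608). Alox5, with the values above, lies on chromosome 6: 116410071 to 116461178. The remaining named falls were Cacng8, a channel subunit (-0.81), Rassf8, a Ras-association protein (-0.72), Emp2, a small membrane protein (-0.70), Dscam, an adhesion molecule (-0.70), Dusp5, a phosphatase of ERK (-0.68), and Pvrl3, a nectin (-0.67). Their limma adjusted p lay between 7.97e-05 for Emp2 and 0.00288 for Pvrl3. Against shRen, sh2865 alone left Dusp5 (limma adjusted p = 0.0588) and Pvrl3 (limma adjusted p = 0.169) outside the threshold. A search of 3′ UTRs, made after the fold changes were seen, tied heptamers to each hairpin: ACATCAA and CACATCA to sh1252, GCACATA and TGCACAT to sh2865, and CTTATCT and TTATCTA to shRen. AGCACAT, which has 6 bases in common with each of the sh2865 heptamers, was rank 3 with sh2865 (z = -9.05) but is not counted as one of them here. Of the 10 genes named for a rise, 2 (Ccr2 and Ccr5) carried an shRen heptamer, but 4 carried one of sh1252 and 4 one of sh2865, against their direction. Of the 9 searched among the 10 named for a fall, 3 (Angptl2, Cpe and Dscam) carried an sh1252 heptamer, none an sh2865 heptamer and 1 (Rassf8) an shRen heptamer.

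Metabolic and stress-response genes made up the lists that were lower with both hairpins, 4 of the 27 tested. Glycolysis and hypoxia genes were lower as a group (mean log2 fold change -0.16, camera adjusted p = 3.46e-08, or 0.157 with an estimated correlation). Of 29 tested, 17 fell and 12 did not pass, and 19 fell adjusted over the list alone. Slc2a1, the glucose transporter, fell by 0.39 (0.000413, limma adjusted p), and the glycolytic enzyme Tpi1 (-0.30), the oxidase Ero1l (-0.39) and the stress gene Ndrg1 (-0.50) were also lower. Fatty acid synthesis and desaturation genes were lower as a group (mean log2 fold change -0.13, camera adjusted p = 6.12e-05, or 0.129 with an estimated correlation). Of 21 tested, 1 rose (Mlxipl), 10 fell and 10 did not pass, and 1 rose and 12 fell adjusted over the list alone. The desaturases Scd2 (-0.63), Fads2 (-0.38) and Fads1 (-0.25), and Acly (-0.22) all fell. Cholesterol synthesis genes were lower as a group (mean log2 fold change -0.12, camera adjusted p = 7.41e-05, or 0.255 with an estimated correlation). Of 25 tested, 12 fell and 13 did not pass, and 13 fell adjusted over the list alone. Mvd (-0.31) and Acat2 (-0.18) act early in that pathway, Sc5d (-0.23) acts late, and Insig1 (-0.23) regulates it. Genes of the unfolded protein and integrated stress responses were lower as a group (mean log2 fold change -0.055, camera adjusted p = 0.0023, or 0.157 with an estimated correlation). Of 38 tested, 2 rose (Atf3 and Ero1lb), 8 fell and 28 did not pass, and 2 rose and 9 fell adjusted over the list alone. Aars (-0.22), a transfer RNA synthetase, and Sdf2l1 (-0.41), a protein of the endoplasmic reticulum, were examples of the falls.

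Lists that were higher numbered 8, most of them of macrophage identity and response. Macrophage markers were higher as a group (mean log2 fold change 0.20, camera adjusted p = 1.23e-05, or 0.169 with an estimated correlation). Of 25 tested, 15 rose, 2 fell (Cd63 and Cd68) and 8 did not pass, and 18 rose and 4 fell adjusted over the list alone. Lyz2, which encodes lysozyme, was at 1278 ± 131 TPM in shRen, 2960.2 ± 66.0 TPM with sh1252 and 1669 ± 217 TPM with sh2865 (log2 fold change 0.80, limma adjusted p = 9.05e-05). Cebpa (0.49), Csf1r (0.46), the receptor that keeps macrophages alive, and Cd14 (0.48) rose as well. Receptors of phagocytosis and of dead cell uptake were higher as a group (mean log2 fold change 0.24, camera adjusted p = 1.23e-05, or 0.255 with an estimated correlation). Of 32 tested, 16 rose, 1 fell (Mfge8) and 15 did not pass, and 20 rose and 1 fell adjusted over the list alone. Besides Clec7a, the endotoxin receptor Tlr4 (0.34) and Sirpa (0.25), which reads the signal that stops engulfment, were among the rises. Chemokines and their receptors were higher as a group (mean log2 fold change 0.48, camera adjusted p = 7.53e-05, or 0.129 with an estimated correlation). Of 18 tested, 10 rose, 1 fell (Ccl5) and 7 did not pass, with either adjustment. Ccl9 (0.42) joined Ccr2, Cx3cr1 and Ccl6. Inflammatory cytokines and genes of classical activation were higher as a group (mean log2 fold change 0.22, camera adjusted p = 0.000238, or 0.129 with an estimated correlation). Of 17 tested, 9 rose and 8 did not pass, and 10 rose adjusted over the list alone. Cybb (0.75), the oxidase subunit behind the respiratory burst, Cd86 (0.58) and Irf5 (0.30) rose. MHC class II presentation genes were higher as a group (mean log2 fold change 0.28, camera adjusted p = 0.0449, or 0.255 with an estimated correlation, and camera adjusted p up to 0.0729 without AN12-1). Of 8 tested, 3 rose (Ctss, H2-DMa and Cd74), 1 fell (Ifi30) and 4 did not pass, and 4 rose and 1 fell adjusted over the list alone. Ctss (0.38), which cleaves the invariant chain, and Cd74 (0.34), that chain, rose. Ifi30 fell (-0.17), but was higher with sh1252 (0.17 without AN12-2). H2-DMb1, a subunit of the peptide exchanger, did not pass (log2 fold change 0.12, limma adjusted p = 0.207). Dendritic cell markers were higher as a group (mean log2 fold change 0.26, camera adjusted p = 0.0224, or 0.157 with an estimated correlation). Of 7 tested, 3 rose (Zbtb46, Irf4 and Itgax) and 4 did not pass, and 4 rose adjusted over the list alone. Bst2 did not pass (log2 fold change 0.032, limma adjusted p = 0.745).

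Immediate early and heat shock genes were higher as a group (mean log2 fold change 0.27, camera adjusted p = 0.00652, or 0.269 with an estimated correlation). Of 27 tested, 11 rose, 3 fell (Hsph1, Fosl1 and Hspe1) and 13 did not pass, and 12 rose and 4 fell adjusted over the list alone. Klf6 (0.51), Atf3 (0.38), Junb (0.20) and Ier5 (0.21) rose. Ribosomal protein genes were higher as a group (mean log2 fold change 0.058, camera adjusted p = 0.00095, or 0.244 with an estimated correlation). Of 64 tested, 7 rose and 57 did not pass, and no member passed adjusted over the list alone. Limma gave 16 of the 64 ribosomal protein genes an unadjusted p under 0.05, and Rpl7 (0.10), Rps25 (0.11), Rpl36 (0.10) and Rplp2 (0.13) had the smallest p. Many ribosomal protein genes have near-identical pseudogenes, which makes their levels uncertain where the counting split reads. With quantile normalization the ribosomal list was at a camera adjusted p = 0.0679. Of the 12 lists called for both hairpins, those that camera did not call with sh1252 alone were the dendritic (0.0835), immediate early (0.702), ribosomal (0.513) and stress response (0.0541) lists, and with sh2865 alone the dendritic (0.36) and MHC class II (0.297) lists (camera adjusted p). Of the list members named with values for both hairpins, Abcg1, Klf6, Sqstm1, Tlr4 and Tnf rose and carried an shRen heptamer, and Acly, Cd44, Ei24, Ero1l, Sc5d and Scd2 fell and carried a heptamer of sh1252 or sh2865. Against their direction, Abcg1, Cd86, Cybb and Mcl1 rose with an sh1252 or sh2865 heptamer and Acly, Hmox1 and Sc5d fell with an shRen heptamer.

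Genes of alternative activation did not pass (mean log2 fold change 0.21, camera adjusted p = 0.12, or 0.454 with an estimated correlation). Of 16 tested, 6 rose, 1 fell (Cd200r1) and 9 did not pass, and 7 rose and 1 fell adjusted over the list alone. Il4ra (0.33), the receptor for interleukin-4, was among the rises. Antioxidant genes and NRF2 targets did not pass (mean log2 fold change -0.0086, camera adjusted p = 0.144, or 0.531 with an estimated correlation). Of 35 tested, 3 rose (Sqstm1, Cybb and Gsr), 5 fell (Hmox1, Pgd, Me1, Gpx1 and Taldo1) and 27 did not pass, and 4 rose and 5 fell adjusted over the list alone. Sqstm1 (0.40) rose and Hmox1 (-0.53), which breaks down haem, fell. Taldo1 was above shRen with sh1252. Apoptosis and cell death genes did not pass (mean log2 fold change 0.10, camera adjusted p = 0.0945, or 0.255 with an estimated correlation). Of 34 tested, 8 rose, 3 fell (Diablo, Bax and Bak1) and 23 did not pass, and 9 rose and 3 fell adjusted over the list alone. Mcl1 (0.40) rose. DNA replication genes did not pass (mean log2 fold change 0.035, camera adjusted p = 0.576, or 0.818 with an estimated correlation). Of 43 tested, 4 rose (Pola1, E2f2, Gins3 and Uhrf1), 5 fell (Mcm7, Rrm2, Pole, Chaf1b and Rfc3) and 34 did not pass, with either adjustment. Mitosis genes did not pass (mean log2 fold change -0.015, camera adjusted p = 0.173, or 0.779 with an estimated correlation). Of 44 tested, 4 fell (Cdc25c, Plk1, Bub3 and Ccna2) and 40 did not pass, and 2 fell adjusted over the list alone. Genes of cholesterol uptake, storage and efflux did not pass (mean log2 fold change 0.061, camera adjusted p = 0.969, or 0.968 with an estimated correlation). Of 21 tested, 5 rose (Cd36, Apoc1, Apoe, Npc2 and Abcg1), 4 fell (Fabp5, Scarb1, Cd68 and Nceh1) and 12 did not pass, and 6 rose and 4 fell adjusted over the list alone. Extracellular matrix and protease genes did not pass (mean log2 fold change 0.10, camera adjusted p = 0.477, or 0.766 with an estimated correlation). Of 20 tested, 6 rose, 2 fell (Spp1 and Cd44) and 12 did not pass, and 7 rose and 2 fell adjusted over the list alone. Thbs1 (0.97) rose, and Spp1 (-0.66) and Cd44 (-0.32) fell.

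Eicosanoid and lipoxygenase genes did not pass (mean log2 fold change 0.0063, camera adjusted p = 0.766, or 0.851 with an estimated correlation). Of 19 tested, 1 rose (Ltc4s), 3 fell (Alox5, Cbr1 and Ptges2) and 15 did not pass, and 2 rose and 3 fell adjusted over the list alone. The sign of the list differed between measures (median 0.018, mean 0.0063, camera direction lower), and Ltc4s (0.62), which makes leukotriene C from the product of Alox5, rose while Cbr1 (-0.29) fell. Lysosome genes did not pass (mean log2 fold change 0.0081, camera adjusted p = 0.56, or 0.818 with an estimated correlation). Of 40 tested, 7 rose, 8 fell and 25 did not pass, with either adjustment. These measures differed in sign too (median -0.0058, mean 0.0081, camera direction lower): the proteases Ctsh (0.53) and Ctsc (0.38) rose and Cd63 (-0.52) fell. MHC class I presentation genes did not pass (mean log2 fold change 0.0045, camera adjusted p = 0.848, or 0.919 with an estimated correlation). Of 16 tested, 1 rose (Tapbp), 2 fell (Nlrc5 and H2-K1) and 13 did not pass, with either adjustment. The sign was again unclear (median 0.028, mean 0.0045, camera direction lower). Neutrophil and granulocyte progenitor markers did not pass (mean log2 fold change 0.25, camera adjusted p = 0.477, or 0.597 with an estimated correlation). Of 5 tested, 1 rose (Csf3r), 1 fell (Cebpe) and 3 did not pass, with either adjustment. Nuclear genes of oxidative phosphorylation did not pass (mean log2 fold change -0.012, camera adjusted p = 0.348, or 0.779 with an estimated correlation). Of 58 tested, 3 fell (Uqcrc2, Cyc1 and Atp5b) and 55 did not pass, and 2 fell adjusted over the list alone. Targets of p53 did not pass (mean log2 fold change 0.061, camera adjusted p = 0.667, or 0.818 with an estimated correlation). Of 26 tested, 5 rose (Sesn1, Btg2, Bbc3, Xpc and Cdkn1a), 6 fell and 15 did not pass, and 7 rose and 6 fell adjusted over the list alone. Btg2 (0.80) rose, and Ei24 (-0.34) fell. Replication-dependent histones did not pass (mean log2 fold change 0.12, camera adjusted p = 0.576, or 0.818 with an estimated correlation). Of 37 tested, 1 fell (Hist1h2bc) and 36 did not pass, with either adjustment. Interferon-stimulated genes did not pass (mean log2 fold change -0.019, camera adjusted p = 0.56, or 0.779 with an estimated correlation). Of 30 tested, 1 rose (Ifi204), 1 fell (Oasl1) and 28 did not pass, with either adjustment. Where 5 or fewer members of a list passed in a direction, they are named here and in the later comparisons, and those outside the naming rule were chosen after their values were seen.

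Several genes of macrophage activation and cholesterol handling were named whatever their result. Tnf, the inflammatory cytokine, was at 17.4 ± 0.856 TPM in shRen, 18.3 ± 0.677 TPM with sh1252 and 22.8 ± 1.85 TPM with sh2865 (log2 fold change 0.22, limma adjusted p = 0.0166). Cd36, a scavenger receptor that takes up oxidized lipoprotein, was at 80.1 ± 16.5 TPM in shRen, 142 ± 11.1 TPM with sh1252 and 96.7 ± 6.61 TPM with sh2865 (log2 fold change 0.56, limma adjusted p = 0.00709). Abcg1, which exports cholesterol, was at 16.9 ± 2.129 TPM in shRen, 17.3 ± 1.51 TPM with sh1252 and 23.8 ± 1.67 TPM with sh2865 (log2 fold change 0.25, limma adjusted p = 0.0429), and its partner Abca1 did not pass (log2 fold change 0.092, limma adjusted p = 0.373). Arg1 and Mrc1, markers of alternative activation, did not pass (limma adjusted p = 0.705 and 0.378, log2 fold changes 0.15 and 0.23), nor did Ccl2, the ligand of Ccr2 (log2 fold change -0.015, limma adjusted p = 0.948). Nos2, which makes nitric oxide, was at 0.00739, 0.0166 and 0.0248 TPM and Il1b, a cytokine of the inflammasome, at 0, 0.144 and 0.131 TPM in shRen, sh1252 and sh2865, both too low to be tested.

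As to limits, leaving out single libraries gave between 1487 (without ANR-3) and 2237 (without AN12-3) changed genes, treating the knockdown libraries as 1 group of 6 gave 734, and weighting the libraries by their spread gave 3522. The fit with 1 group ended 62 limma calls of genes named for both hairpins, with values here those of Abcg1, Acat2, Acly, Atf3, Cbr1, Cd14, Cd36, Csf1r, Ctss, Cybb, Hmox1, Ifi30, Ltc4s, Ndrg1, Pvrl3, Rpl36, Rpl7, Rplp2, Rps25, Slc2a1, Socs3, Thbs1 and Tnf (adjusted p from 0.0504 to 0.526). Leaving out a single library ended the limma calls of the following genes, given with the highest adjusted p and the library left out: Abcg1 (0.119, ANR-2), Rpl36 (0.0771, AN28-1), Rpl7 (0.0653, ANR-3), Rplp2 (0.0753, ANR-2), Rps25 (0.0731, AN28-2) and Socs3 (0.0715, ANR-3). The same was seen for Tnf (0.0535, ANR-2). Of the genes named without values, Atp5b, Bub3, Ccl5, Ccna2, Cd200r1, Cd68, Cdkn1a, Chaf1b, Fosl1, Gins3, H2-K1, Hspe1, Itgax, Nceh1, Npc2, Pole, Rfc3, Rrm2, Scarb1, Taldo1 and Uhrf1 lost theirs too (highest limma adjusted p from 0.0507 to 0.13).

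**Figure D1:**
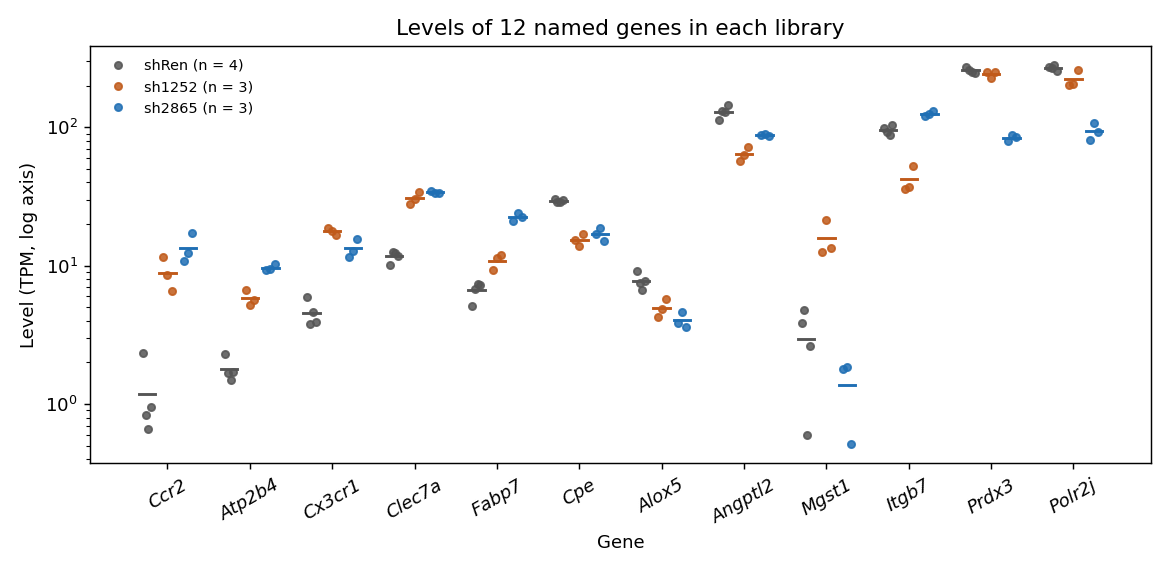
Levels of 12 named genes in each library, in TPM on a log axis. Each point is 1 library (grey, shRen, 4 libraries; orange, sh1252, 3; blue, sh2865, 3), and short bars are group means. The Ccr2, Cx3cr1, Atp2b4 and Clec7a points of both hairpins lie above all shRen points, while Mgst1 is highest with sh1252 and Prdx3 lowest with sh2865.

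Hairpin sh1252 was set against shRen on its own. Camera called macrophage, phagocytic and MHC class II lists higher and glycolytic and lipid-synthesis lists lower with the preset correlation, but 0 of 27 with an estimated one (6 at an unadjusted p under 0.05, lowest adjusted p = 0.193). Limma passed 3254 of 11534 genes (1929 rose and 1325 fell, or 1477 and 1652 with quantile normalization, with 4692 at an unadjusted p under 0.05), of which 80 changed at least 2-fold, and the median size of the changes was 0.30. Mgst1 (chromosome 6: 138140527 to 138156755), a glutathione transferase of membranes, was at 2.96 ± 1.80 TPM in shRen and 15.8 ± 4.84 TPM with sh1252 (log2 fold change 2.20, limma adjusted p = 0.00245). Hp (chromosome 8: 109575128 to 109579172), which encodes the haemoglobin carrier haptoglobin, was at 5.84 ± 2.57 TPM in shRen and 23.1 ± 3.04 TPM with sh1252 (log2 fold change 1.88, limma adjusted p = 0.00018). Abcd2 (chromosome 15: 91145871 to 91192007), a peroxisomal transporter of fatty acids, was at 7.65 ± 0.375 TPM in shRen and 24.5 ± 2.96 TPM with sh1252 (log2 fold change 1.56, limma adjusted p = 5.22e-06), and it carried sh1252 and shRen heptamers. Ccr2 (2.20) and Cx3cr1 (1.77) completed the largest rises (limma adjusted p = 0.00017 and 2.06e-05). Itgb7 (chromosome 15: 102215994 to 102233405), an integrin chain of homing lymphocytes, was at 95.8 ± 7.12 TPM in shRen and 42.0 ± 9.51 TPM with sh1252 (log2 fold change -1.19, limma adjusted p = 7.4e-05), and Rgs16 (chromosome 1: 153740353 to 153745468), which shortens G protein signals, was at 9.37 ± 2.43 TPM in shRen and 3.25 ± 1.41 TPM with sh1252 (log2 fold change -1.31, limma adjusted p = 0.00167). The microRNA genes Mir6941 (-2.52), Mir7666 (-2.27) and Mir763 (-1.29) also passed (limma adjusted p = 0.0142, 0.0387 and 0.00428), but their levels are uncertain, since such short genes can take reads of an overlapping host transcript. Neither Itgb7 nor Rgs16 carried an sh1252 heptamer, and the microRNA genes had no 3′ UTR to search.

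Of the 27 lists, 6 were higher and 4 lower with sh1252. Macrophage markers were higher as a group (mean log2 fold change 0.32, camera adjusted p = 1.54e-05, or 0.193 with an estimated correlation). Of 25 tested, 17 rose, 1 fell (Cd63) and 7 did not pass, and 18 rose and 1 fell adjusted over the list alone. Lyz2 (1.22), Cd14 (0.86), Csf1r (0.72) and Cebpa (0.64) rose. Receptors of phagocytosis and of dead cell uptake were higher as a group (mean log2 fold change 0.30, camera adjusted p = 0.000566, or 0.434 with an estimated correlation). Of 32 tested, 18 rose, 3 fell (Mfge8, Itgb2 and Itgav) and 11 did not pass, and 20 rose and 3 fell adjusted over the list alone. Clec7a (1.33) and the inhibitory antibody receptor Fcgr2b (0.60) rose. Chemokines and their receptors were higher as a group (mean log2 fold change 0.52, camera adjusted p = 0.00594, or 0.193 with an estimated correlation). Of 18 tested, 10 rose and 8 did not pass, and 11 rose and 1 fell adjusted over the list alone. Ccr5 (1.16) and Ccl9 (0.39) were among the rises. Inflammatory cytokines and genes of classical activation were higher as a group (mean log2 fold change 0.26, camera adjusted p = 0.00609, or 0.193 with an estimated correlation). Of 17 tested, 10 rose and 7 did not pass, and 11 rose adjusted over the list alone. Cybb (1.15), Cd86 (0.85), Tnfaip2 (0.35) and the inflammasome sensor Nlrp3 (0.35) rose. MHC class II presentation genes were higher as a group (mean log2 fold change 0.41, camera adjusted p = 0.00857, or 0.193 with an estimated correlation). Of 8 tested, 3 rose (Ctss, Cd74 and H2-DMa) and 5 did not pass, and 5 rose adjusted over the list alone. Ifi30 and H2-DMb1 were outside the threshold (limma adjusted p = 0.0652 and 0.0872). Interferon-stimulated genes were higher as a group (mean log2 fold change 0.18, camera adjusted p = 0.039, or 0.246 with an estimated correlation, and camera adjusted p up to 0.0865 without AN12-3). Of 30 tested, 8 rose, 1 fell (Oasl1) and 21 did not pass, and 9 rose and 1 fell adjusted over the list alone. Ifi204 (0.69), Oas2 (0.38) and Bst2 (0.27) rose.

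Glycolysis and hypoxia genes were lower as a group (mean log2 fold change -0.22, camera adjusted p = 3.51e-08, or 0.193 with an estimated correlation). Of 29 tested, 1 rose (Egln3), 15 fell and 13 did not pass, and 1 rose and 17 fell adjusted over the list alone. Slc2a1 (-0.60), Ndrg1 (-0.86), the phosphofructokinase Pfkp (-0.39) and Tpi1 (-0.44) fell. Fatty acid synthesis and desaturation genes were lower as a group (mean log2 fold change -0.12, camera adjusted p = 0.00623, or 0.193 with an estimated correlation). Of 21 tested, 1 rose (Mlxipl), 7 fell and 13 did not pass, with either adjustment. Scd2 (-0.86), Fads1 (-0.32), Fads2 (-0.35) and the carboxylase Acaca (-0.32) fell. Cholesterol synthesis genes were lower as a group (mean log2 fold change -0.08, camera adjusted p = 0.0132, or 0.526 with an estimated correlation). Of 25 tested, 3 rose (Pmvk, Tm7sf2 and Ggps1), 7 fell and 15 did not pass, and 3 rose and 11 fell adjusted over the list alone. Dhcr24 (-0.60), which completes the pathway, Acat2 (-0.31) and Insig1 (-0.25) fell. Nuclear genes of oxidative phosphorylation were lower as a group (mean log2 fold change -0.052, camera adjusted p = 0.00893, or 0.434 with an estimated correlation, and camera adjusted p up to 0.0759 without AN12-1). Of 58 tested, 1 rose (Atp5f1), 7 fell and 50 did not pass, and 1 rose and 6 fell adjusted over the list alone. Uqcrc2 (-0.37) and Cyc1 (-0.18) of complex III and Sdhd (-0.17) of complex II fell. Genes named with values for this hairpin that moved with a matching heptamer were Abcd2, Ccr2, Ccr5, Scd2 and Uqcrc2. In the other direction, Abcd2, Ccr2, Ccr5 and Cybb rose with an sh1252 heptamer. As to limits, the count of changed genes was 1913 without AN12-1 and 2118 without AN12-2. Omission of single libraries ended the limma calls of Bst2 (0.0716, AN12-1), Mir6941 (0.0708, AN12-1) and Mir7666 (0.116, AN12-3). Among those named without values, Egln3, Ggps1, Itgav, Itgb2, Mlxipl, Pmvk and Tm7sf2 lost theirs too (highest limma adjusted p from 0.0737 to 0.151).

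Hairpin sh2865 was set against shRen in the same way. By camera with the preset correlation early-response and chemokine lists were higher and interferon-stimulated, lysosomal and lipid-synthesis lists lower, and 0 of 27 passed with an estimated one (8 at an unadjusted p under 0.05, lowest adjusted p = 0.107). Limma passed 1658 of 11534 genes (768 rose and 890 fell, or 860 and 794 on the deposited scale, with 3247 at an unadjusted p under 0.05), 36 of them at least 2-fold, and the median size of the changes was 0.32. Prdx3 (chromosome 19: 60864066 to 60874538), the mitochondrial peroxiredoxin, was at 257 ± 10.5 TPM in shRen and 84.2 ± 4.38 TPM with sh2865 (log2 fold change -1.60, limma adjusted p = 4.2e-08) and carried an sh2865 heptamer in its 3′ UTR. Polr2j (chromosome 5: 136116691 to 136122947), a subunit of RNA polymerase II, was at 269.8 ± 11.1 TPM in shRen and 93.5 ± 12.9 TPM with sh2865 (log2 fold change -1.53, limma adjusted p = 9.75e-06) and carried none. Nxt2 (chromosome X: 142226770 to 142239700), which takes part in RNA export, was at 31.2 ± 4.32 TPM in shRen and 13.5 ± 1.82 TPM with sh2865 (log2 fold change -1.15, limma adjusted p = 7.36e-05). Uchl1 (-1.05), a ubiquitin hydrolase, carried no sh2865 heptamer, while Cacybp (-1.03), which guides beta-catenin to degradation, did (limma adjusted p = 0.00323 and 4.81e-05). Sell (chromosome 1: 164061987 to 164082930), the selectin with which leukocytes roll on vessel walls, was at 6.11 ± 2.05 TPM in shRen and 19.6 ± 0.377 TPM with sh2865 (log2 fold change 1.58, limma adjusted p = 0.00025), and Dusp1 (chromosome 17: 26505591 to 26508472), a phosphatase of stress kinases, was at 55.7 ± 23.2 TPM in shRen and 148 ± 16.0 TPM with sh2865 (log2 fold change 1.51, limma adjusted p = 0.0302). Ccr2 (2.75), Atp2b4 (1.94) and Fabp7 (1.63) were the other largest rises (limma adjusted p = 6.94e-05, 7.11e-06 and 1.88e-05).

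Lists that were higher with sh2865 numbered 9. Ribosomal protein genes were higher as a group (mean log2 fold change 0.093, camera adjusted p = 1.21e-06, or 0.107 with an estimated correlation). Of 64 tested, 4 rose (Rpl36, Rpl12, Rpl27 and Rplp2) and 60 did not pass, and 1 rose adjusted over the list alone. With quantile normalization this list was at a camera adjusted p = 0.0968. Immediate early and heat shock genes were higher as a group (mean log2 fold change 0.45, camera adjusted p = 2.63e-05, or 0.128 with an estimated correlation). Of 27 tested, 11 rose and 16 did not pass, and 17 rose and 2 fell adjusted over the list alone. Klf2 (1.51), Klf4 (0.75), Klf6 (0.57) and Egr1 (0.66) rose. Chemokines and their receptors were higher as a group (mean log2 fold change 0.43, camera adjusted p = 0.000174, or 0.107 with an estimated correlation). Of 18 tested, 9 rose, 1 fell (Ccl5) and 8 did not pass, and 11 rose and 3 fell adjusted over the list alone. Ccl6 (1.16), Cx3cr1 (1.37) and Ccl9 (0.44) rose beside Ccr2. Receptors of phagocytosis and of dead cell uptake were higher as a group (mean log2 fold change 0.18, camera adjusted p = 0.000285, or 0.321 with an estimated correlation). Of 32 tested, 6 rose, 1 fell (Gas6) and 25 did not pass, and 12 rose and 3 fell adjusted over the list alone. Clec7a (1.47), Tlr4 (0.50), Itgam (0.28) and the scavenger receptor Stab1 (0.39) rose. Inflammatory cytokines and genes of classical activation were higher as a group (mean log2 fold change 0.19, camera adjusted p = 0.00127, or 0.121 with an estimated correlation). Of 17 tested, 7 rose, 2 fell (Tnfaip2 and Stat1) and 8 did not pass, and 10 rose and 2 fell adjusted over the list alone. Irf5 (0.37) and Tnf (0.37) rose. Extracellular matrix and protease genes were higher as a group (mean log2 fold change 0.20, camera adjusted p = 0.00161, or 0.128 with an estimated correlation). Of 20 tested, 8 rose, 2 fell (Spp1 and Cd44) and 10 did not pass, and 11 rose and 2 fell adjusted over the list alone. Mmp9 (1.21), Lgals3 (0.45) and the sheddase Adam10 (0.31) rose. DNA replication genes were higher as a group (mean log2 fold change 0.064, camera adjusted p = 0.00873, or 0.227 with an estimated correlation). Of 43 tested, 5 rose (E2f2, Pola1, Mcm3, Rpa2 and Uhrf1), 1 fell (Mcm7) and 37 did not pass, with either adjustment. Macrophage markers were higher as a group (mean log2 fold change 0.083, camera adjusted p = 0.02, or 0.389 with an estimated correlation, and camera adjusted p up to 0.128 without ANR-1). Of 25 tested, 7 rose, 3 fell (Cd63, Cd68 and Mpeg1) and 15 did not pass, and 9 rose and 4 fell adjusted over the list alone. Apoptosis and cell death genes were higher as a group (mean log2 fold change 0.093, camera adjusted p = 0.0485, or 0.227 with an estimated correlation, and camera adjusted p up to 0.0959 without ANR-1). Of 34 tested, 8 rose, 2 fell (Diablo and Bax) and 24 did not pass, and 10 rose and 2 fell adjusted over the list alone. Mcl1 (0.35), which protects cells, and Bcl2l11 (0.41), which kills them, both rose.

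Lists that were lower numbered 8. Interferon-stimulated genes were lower as a group (mean log2 fold change -0.22, camera adjusted p = 0.000285, or 0.107 with an estimated correlation). Of 30 tested, 1 rose (Ifi204), 10 fell and 19 did not pass, and 1 rose and 14 fell adjusted over the list alone. Irf9 (-0.34), Stat1 (-0.26) and Ifi27l2a (-0.43) fell. Lysosome genes were lower as a group (mean log2 fold change -0.10, camera adjusted p = 0.00057, or 0.262 with an estimated correlation). Of 40 tested, 2 rose (Ctsh and Ctsc), 12 fell and 26 did not pass, and 2 rose and 15 fell adjusted over the list alone. Atp6v1a (-0.34), Scarb2 (-0.44) and Gpnmb (-0.54) fell. Cholesterol synthesis genes were lower as a group (mean log2 fold change -0.15, camera adjusted p = 5.14e-05, or 0.227 with an estimated correlation). Of 25 tested, 10 fell and 15 did not pass, and 1 rose and 15 fell adjusted over the list alone. Sqle (-0.23), Msmo1 (-0.40), Mvd (-0.37) and Sc5d (-0.30) fell. Fatty acid synthesis and desaturation genes were lower as a group (mean log2 fold change -0.15, camera adjusted p = 0.000285, or 0.107 with an estimated correlation). Of 21 tested, 1 rose (Mlxipl), 7 fell and 13 did not pass, and 1 rose and 11 fell adjusted over the list alone. Acly (-0.38), Me1 (-0.64), Fads2 (-0.40) and the elongase Elovl5 (-0.47) fell. Glycolysis and hypoxia genes were lower as a group (mean log2 fold change -0.10, camera adjusted p = 0.0019, or 0.321 with an estimated correlation). Of 29 tested, 6 fell and 23 did not pass, and 2 rose and 11 fell adjusted over the list alone. Egln3 (-0.77), Ero1l (-0.38), Aldoc (-0.39) and P4ha1 (-0.21) fell. Genes of the unfolded protein and integrated stress responses were lower as a group (mean log2 fold change -0.088, camera adjusted p = 0.00294, or 0.14 with an estimated correlation). Of 38 tested, 1 rose (Ero1lb), 9 fell and 28 did not pass, and 1 rose and 10 fell adjusted over the list alone. Mthfd2 (-0.35), Sars (-0.22) and Aars (-0.23) fell. Antioxidant genes and NRF2 targets were lower as a group (mean log2 fold change -0.074, camera adjusted p = 0.00531, or 0.227 with an estimated correlation). Of 35 tested, 4 rose (Gsr, Sqstm1, Gpx3 and Cybb), 14 fell and 17 did not pass, and 4 rose and 15 fell adjusted over the list alone. Hmox1 (-0.94) and Taldo1 (-0.34) fell. Mitosis genes were lower as a group (mean log2 fold change -0.065, camera adjusted p = 0.00531, or 0.432 with an estimated correlation, and camera adjusted p up to 0.0591 without AN28-3). Of 44 tested, 7 fell and 37 did not pass, and 1 rose and 9 fell adjusted over the list alone. Cdc25c (-0.41), Prc1 (-0.30), Ube2c (-0.22) and Incenp (-0.13) fell. Matching heptamers were carried by Acly, Aldoc, Cacybp, Elovl5, Prc1, Prdx3, Sars, Scarb2, Stat1 and Taldo1 among the genes named with values that fell and by Ccr2, Klf6, Mmp9, Tlr4 and Tnf among those that rose. Conversely, Atp2b4, Cx3cr1, Lgals3 and Sell rose with an sh2865 heptamer and Acly, Gpnmb, Hmox1 and Sc5d fell with an shRen heptamer. Hmox1, Mthfd2 and Nxt2 fell with the uncounted AGCACAT. As to limits, the count of changed genes was 914 without AN28-1, 1006 without AN28-2 and 2790 with libraries weighted by their spread. Calls that limma lost when single libraries were left out were Dusp1 (0.0916, AN28-3), Ifi27l2a (0.0921, AN28-1), Incenp (0.126, AN28-1), P4ha1 (0.123, AN28-2), Sqle (0.0508, AN28-1) and Stat1 (0.0953, AN28-1). Of those named without values, Ccl5, Cybb, Gas6, Gpx3, Ifi204, Mpeg1, Rpa2, Rpl12, Rpl27, Rplp2 and Uhrf1 lost theirs too (highest limma adjusted p from 0.0552 to 0.145).

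The hairpins were also compared with each other, since hairpins against the same gene should move the same transcripts. The lysosomal and interferon-stimulated lists were higher with sh1252 and the matrix, early-response and DNA replication lists lower by camera with the preset correlation, and 0 of 27 passed with an estimated one (3 at an unadjusted p under 0.05, lowest adjusted p = 0.145). Limma passed 3250 of 11534 genes, 2016 higher and 1234 lower with sh1252 than with sh2865 (1553 and 1633 with quantile normalization, and 4655 at an unadjusted p under 0.05), 123 of them at least 2-fold, with a median size of 0.34. Mgst1 was at 15.8 ± 4.84 TPM with sh1252 and 1.38 ± 0.757 TPM with sh2865 (log2 fold change 2.84, limma adjusted p = 0.000791). S1pr1 (chromosome 3: 115710433 to 115715055), the receptor by which leukocytes leave tissue, was at 20.1 ± 1.25 TPM with sh1252 and 3.89 ± 0.483 TPM with sh2865 (log2 fold change 2.11, limma adjusted p = 5.74e-07) and carried an sh2865 heptamer, as did Hp. Ephx1 (chromosome 1: 180989556 to 181017569), an epoxide hydrolase, was at 33.7 ± 1.66 TPM with sh1252 and 7.63 ± 0.828 TPM with sh2865 (log2 fold change 2.01, limma adjusted p = 2.64e-07) and carried none. Fam167b (1.73), of unknown function, and Hp (1.54) were the other largest positive differences (limma adjusted p = 2.42e-05 and 0.000753). Sell was at 4.32 ± 0.840 TPM with sh1252 and 19.6 ± 0.377 TPM with sh2865 (log2 fold change -1.97, limma adjusted p = 7.11e-05), and Itgb7 was at 42.0 ± 9.51 TPM with sh1252 and 125 ± 6.08 TPM with sh2865 (log2 fold change -1.58, limma adjusted p = 2.46e-05). Crip1 (-1.55), a small zinc-binding protein, Mmp9 (-1.42) and Mir6941 (-2.17) were also lower (limma adjusted p = 0.000899, 0.000487 and 0.0359), the last with the uncertainty of a short gene.

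Of the 27 lists, 6 were higher and 6 lower with sh1252 than with sh2865. Lysosome genes were higher as a group (mean log2 difference 0.22, camera adjusted p = 5.51e-05, or 0.302 with an estimated correlation). Of 40 tested, 23 were higher, 2 were lower (Glb1 and Gaa) and 15 did not pass, and 24 higher and 3 lower adjusted over the list alone. Gpnmb (0.96), Atp6v1a (0.47) and Mitf (0.79), a factor that drives lysosomal genes, were higher. Interferon-stimulated genes were higher as a group (mean log2 difference 0.40, camera adjusted p = 5.51e-05, or 0.145 with an estimated correlation). Of 30 tested, 16 were higher, 1 was lower (Oasl1) and 13 did not pass, and 19 higher and 1 lower adjusted over the list alone. Oas2 (0.69), Irf9 (0.56), Bst2 (0.48) and Ifi27l2a (0.66) were higher. Macrophage markers were higher as a group (mean log2 difference 0.24, camera adjusted p = 0.00256, or 0.302 with an estimated correlation). Of 25 tested, 14 were higher, 2 were lower (Lgals3 and Itgam) and 9 did not pass, and 14 higher and 3 lower adjusted over the list alone. Lyz2 (0.83) and Cd14 (0.78) were higher and Lgals3 (-0.49) lower. Antioxidant genes and NRF2 targets were higher as a group (mean log2 difference 0.13, camera adjusted p = 0.012, or 0.302 with an estimated correlation). Of 35 tested, 18 were higher, 3 were lower (Gpx3, Sod1 and Tkt) and 14 did not pass, and 19 higher and 5 lower adjusted over the list alone. Hmox1 (0.81), Taldo1 (0.48) and Gss (0.37), which makes glutathione, were higher. MHC class I presentation genes were higher as a group (mean log2 difference 0.19, camera adjusted p = 0.0166, or 0.302 with an estimated correlation). Of 16 tested, 7 were higher and 9 did not pass, with either adjustment. H2-M3 (0.60), Nlrc5 (0.43) and the peptide transporter Tap2 (0.52) were higher. MHC class II presentation genes were higher as a group (mean log2 difference 0.27, camera adjusted p = 0.0476, or 0.302 with an estimated correlation, and camera adjusted p up to 0.0731 without AN28-1). Of 8 tested, 3 were higher (Ifi30, Ctss and Cd74) and 5 did not pass, with either adjustment.

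Glycolysis and hypoxia genes were lower as a group (mean log2 difference -0.12, camera adjusted p = 0.00069, or 0.302 with an estimated correlation). Of 29 tested, 3 were higher (Egln3, Aldoc and Hk2), 14 were lower and 12 did not pass, and 3 higher and 15 lower adjusted over the list alone. Ndrg1 (-0.70), Pfkp (-0.37) and the lactate exporter Slc16a3 (-0.39) were lower, but Egln3 was higher (1.20). Nuclear genes of oxidative phosphorylation were lower as a group (mean log2 difference -0.079, camera adjusted p = 0.000746, or 0.302 with an estimated correlation). Of 58 tested, 1 was higher (Atp5f1), 10 were lower and 47 did not pass, and 1 higher and 7 lower adjusted over the list alone. Uqcrc2 (-0.27), Sdhd (-0.20) and Atp5g3 (-0.21) were lower. Extracellular matrix and protease genes were lower as a group (mean log2 difference -0.20, camera adjusted p = 0.00107, or 0.302 with an estimated correlation). Of 20 tested, 1 was higher (Thbs1), 9 were lower and 10 did not pass, and 1 higher and 10 lower adjusted over the list alone. S100a4 (-0.67) and Vim (-0.55) were lower. DNA replication genes were lower as a group (mean log2 difference -0.059, camera adjusted p = 0.00166, or 0.302 with an estimated correlation). Of 43 tested, 4 were higher (Ccne1, E2f1, Gins1 and Pola1), 13 were lower and 26 did not pass, with either adjustment. Mcm3 (-0.24), Rad51 (-0.27) and Dut (-0.19) were lower. Immediate early and heat shock genes were lower as a group (mean log2 difference -0.35, camera adjusted p = 0.00204, or 0.302 with an estimated correlation). Of 27 tested, 1 was higher (Atf3), 8 were lower and 18 did not pass, with either adjustment. Egr1 (-0.96), Egr3 (-0.59) and Klf4 (-0.73) were lower. Ribosomal protein genes were lower as a group (mean log2 difference -0.07, camera adjusted p = 0.00204, or 0.302 with an estimated correlation). Of 64 tested, 11 were lower and 53 did not pass, and 6 lower adjusted over the list alone. Rps20 (-0.21), Rps14 (-0.15) and Rps17 (-0.17) were lower, but with quantile normalization the list's direction turned and its camera adjusted p was 0.968. Among the genes named with values, Hp, S1pr1 and Taldo1 were higher and carried an sh2865 heptamer, and Dut, Rad51, Rps20, Sell, Slc16a3 and Uqcrc2 lower with an sh1252 heptamer. Conversely, Atp6v1a, Egln3 and Nlrc5 were higher with an sh1252 heptamer and Lgals3, Sell and Slc16a3 lower with an sh2865 heptamer. As to limits, leaving out AN12-1 brought the count of differing genes to 2068. Leaving out single libraries ended the limma calls of Mir6941 (0.14, AN12-1), Rps14 (0.0516, AN12-2) and Rps17 (0.0624, AN12-1). Of those named without values, Aldoc, Cd74, Gaa, Gins1, Glb1, Hk2, Itgam, Pola1 and Tkt lost theirs too (highest limma adjusted p from 0.059 to 0.154).

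Changes common to both hairpins were counted. Limma called 616 genes against shRen with each hairpin in the same direction, 356 up and 260 down, and 146 in opposite directions. Of the 616, 5 changed at least 2-fold with each hairpin: Atp2b4, Ccr2, Clec7a, Cx3cr1 and Gm5483, the last being a predicted gene outside the naming rule and chosen after its values were seen. Independent lists of these sizes would share 128 rising and 102 falling genes. In 100 simulations of unchanged groups against common controls, 0 genes were shared. No gene was changed in them, so hardly any could pass. That 0 therefore does not show how much overlap common controls add among many real calls. Across genes, which are not independent replicates, the fold changes of the hairpins correlated with r = 0.292, and the shared controls alone gave a mean r of 0.431 in the simulations (0.353 to 0.510). The covariance was 0.0191, against 0.00933 in the simulations, a difference of 0.00975. When the 4 shRen libraries were split so that each hairpin had its own 2, the 6 possible splits gave a mean r of 0.127 (0.0625 to 0.181), a mean covariance of 0.00940, and between 56 and 152 shared rises and 46 and 114 shared falls, where independent lists of those sizes would share 14.1 to 63.0 and 12.7 to 46.5. Without AN28-1 the count of shared genes was 364, and it was 1127 with libraries weighted by their spread.

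**Figure D2:**
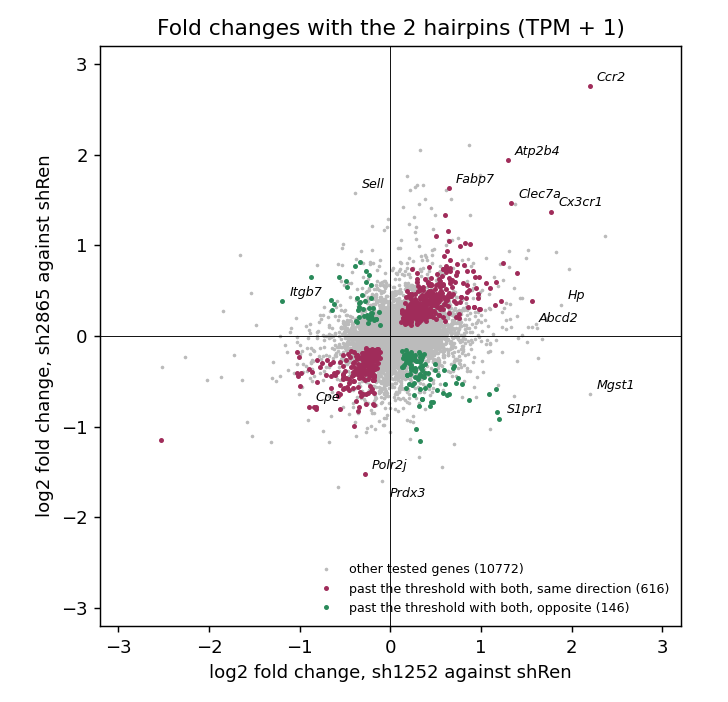
Log2 fold change of each tested gene with sh1252 (horizontal) and with sh2865 (vertical), both against shRen. Purple points are the 616 genes called with both hairpins in the same direction, green the 146 called in opposite directions, and grey the other 10772, and Ccr2 lies farthest along the shared direction.

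**Figure D3:**
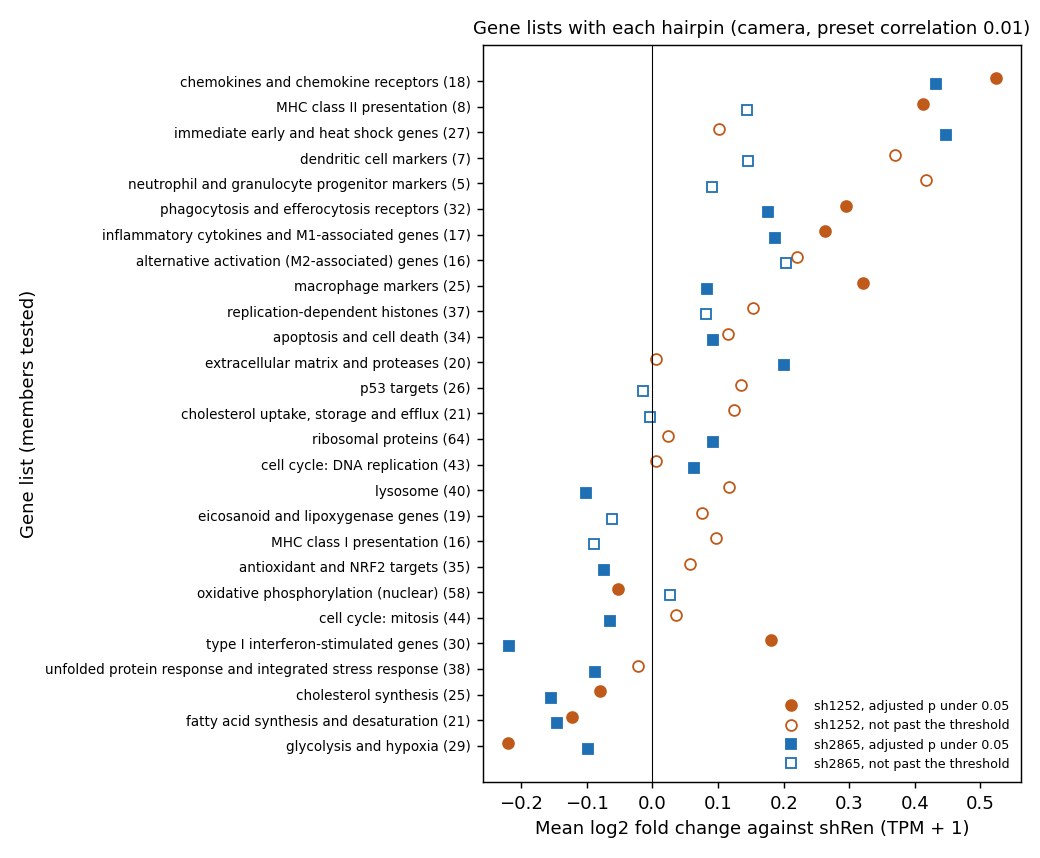
Mean log2 fold change of the members of the 27 gene lists against shRen, with the number of members tested beside each name. Circles are sh1252 and squares sh2865, filled where the camera adjusted p with the preset correlation of 0.01 was under 0.05, and the interferon-stimulated and lysosome lists lie on opposite sides of 0 for the hairpins.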

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

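The rules for single libraries and for gene lists in this part were fixed in advance, the test of entries named by dates was chosen after such names had been seen, and no explanation was tested for any of them. In shRen, 1 library stood apart from the other 3 in 6 of the 166 values examined, and chance alone does so in about 1 in 20. The size of the gap, as a share of the range, is given against a critical value of 0.829. Fcgr2b, the inhibitory antibody receptor, had 67.2 TPM in ANR-1 against 57.4 to 57.9 TPM in the others (0.954), and Card11 had 69.2 TPM in ANR-1 against 52.1 to 54.0 TPM (0.892). Rpl27 was at 1811 TPM in ANR-1 against 1838 TPM or more (0.952), and Rps20 at 1700 TPM in ANR-1 against 1822 to 1847 TPM (0.835). ANR-2 had 171.5 TPM of Cd63 against 157 to 159 TPM in the others (0.863) and 19.1 TPM of Mir6941 against 7.99 to 9.53 TPM (0.862).

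Of the 12 lists called between hairpins by a camera test of the difference itself, these are the 7 whose camera directions against shRen were opposite. Interferon-stimulated genes had a mean log2 fold change of 0.18 with sh1252 and -0.22 with sh2865 (camera adjusted p = 5.51e-05, and 0.145 with an estimated correlation). Lysosome genes had 0.12 and -0.10 (5.51e-05), oxidative phosphorylation genes -0.052 and 0.027 (0.000746), and NRF2 targets 0.057 and -0.074 (0.012). Presentation by MHC class I had means of 0.098 and -0.089 (0.0166), although neither hairpin passed alone. Matrix and protease genes had means of 0.0050 and 0.20 (0.00107), and DNA replication genes 0.0053 and 0.064 (0.00166). For these last lists sh1252 had medians of -0.13 and -0.0090 and a camera direction of lower, so mean, median and test differed in sign. Except for the interferon list, the adjusted p of each difference was 0.302 with an estimated correlation.

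Entries whose names had become calendar dates were outside the comparisons of the report. Of the 27, 17 passed the filter, and limma put 4 of them past the threshold for both hairpins, 5 for sh1252, 4 for sh2865 and 6 for sh1252 against sh2865.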

How the results depend on the processing

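The deposited scale, voom, a replicate block and leaving out genes with a heptamer were chosen after the data were seen. Titles share no replicate numbers between groups, but columns are numbered 1 to 3 in each. In the 9 same-numbered pairs, deviations from the group means correlated at -0.035 to 0.104, and 4 of 9 libraries correlated best with their own number, so the numbers were not taken as pairs. A replicate block on them gave 2218 genes for both hairpins, 3226 for sh1252, 2004 for sh2865, 3898 between hairpins and 683 shared, and other results were not run with it. The groups' last columns, a grouping not fitted, were lowest on the third component (-15.0, -12.4 and -5.47) and deviations correlated at 0.079 to 0.185. Scaling left the median of all genes between -0.012 and 0.034.

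For both hairpins, limma called 2209 genes, and 3522 with array weights, 734 with the knockdown libraries as 1 group of 6, where the difference between the hairpins adds to the spread, and 1209 without genes carrying a heptamer, where 6403 genes were tested because genes without a searched 3′ UTR were left out as well. The exact rank-sum test called 0, with 2254 at an unadjusted p under 0.05, since its smallest possible p of 0.00952, reached by 1102 genes, gave a lowest adjusted p of 0.0997. Voom called 2505 and the deposited scale 2262. Array weights gave 2790 genes for sh2865 (against 1658) and 1127 shared genes (against 616), and the cause was not tested. Without genes carrying a heptamer the counts were 1916 for sh1252, 841 for sh2865, 1764 between hairpins and 343 shared. Split controls gave a mean of 195.5 shared genes, with fewer control libraries in each fit. The balance of calls depended on the scaling. Counts up and down turned to 980 and 1129 with quantile normalization and 1095 and 1168 with median-of-ratios scaling for both hairpins, to 860 and 794 on the deposited scale and 1020 and 940 with voom for sh2865, and with quantile normalization to 1477 and 1652 for sh1252 and 1553 and 1633 between hairpins.

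Leaving out 1 library gave 1487 (without ANR-3) to 2237 (without AN12-3) genes for both hairpins, 1913 (without AN12-1) to 3424 (without ANR-1) for sh1252, 914 (without AN28-1) to 1742 (without ANR-4) for sh2865, 2068 (without AN12-1) to 3542 (without ANR-4) between hairpins, and 364 (without AN28-1 or AN28-2) to 656 (without ANR-1) shared. These fits have fewer libraries. The correlation between hairpins was 0.292, and 0.331 with a pseudocount of 0.1, 0.338 with array weights, 0.127 with split controls, and 0.259 (without AN12-3) to 0.348 (without ANR-1) when a library was left out. Its cause was not tested apart from the shared controls. Alox8 stayed at 0 to 0.00607 TPM, and limma gave it an adjusted p of 0.828 with no filter, while the other limma settings keep the filter and leave it out.

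Camera called 12, 10, 17 and 12 lists in the 4 comparisons and 0 in each with an estimated correlation, with 7, 6, 8 and 3 at an unadjusted p under 0.05. Hairpin sh1252 had 6 lists without genes carrying a heptamer, with fewer genes tested. Leaving out 1 library gave 11 to 15, 9 to 12, 14 to 18 and 11 to 14 lists. Ribosomal protein genes reversed between hairpins with quantile normalization (camera adjusted p = 0.968, main 0.00204), the cause was not tested, and with it they lost their calls for both hairpins (0.0679) and sh2865 (0.0968). The interferon list of sh1252 (0.0598 to 0.237), the apoptosis list of sh2865 (0.0504 to 0.443) and MHC class II for both hairpins (0.0537 to 0.0729) each lost their camera call under several alternatives. Dendritic markers for both hairpins (0.054 to 0.230) and oxidative phosphorylation for sh1252 (0.0759 and 0.443) lost it under a few. Without genes carrying a heptamer, chemokines (0.198), classical activation (0.118) and fatty acid synthesis (0.0516) of sh1252 were not called.

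Of 344 comparisons of a named gene, 333 were called, 228 of them under each alternative run and 105 lost under at least 1, 68 when a library was left out. The rank-sum test, planned for the count of changed genes, was not counted among them. Leaving out 1 library left 286 (without AN28-1) to 312 (without ANR-1) calls, and the other alternatives run over all of them 298 to 332, while 1 group of 6, run for both hairpins only, left 66 of 128. Of the 11 not called, 3 passed under at least 1. Reversals were in genes that were not called: Arg1 in both hairpins was at -0.0021 with array weights and between -0.14 (without ANR-1) and 0.28 (without ANR-4) when a library was left out, Ccl2 between -0.13 (without AN12-3) and 0.051 (without AN12-2), and Bst2 between -0.0045 (without ANR-2) and 0.083 (without ANR-1), and the cause was not tested. Robust moderation has no camera counterpart, and fits of the compared groups only have none for both hairpins together.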

Other observations

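Markers of other lineages were low or scattered. The lists of T and NK cells (3 of 20 tested, highest Cd28 at 25.6 TPM), B cells (1 of 13, Blnk at 77.4 TPM), fibroblasts and epithelium (2 of 17, Tagln at 2.35 TPM), mast cells and basophils (0 of 11, Hdc at 0.361 TPM) and erythroid cells and megakaryocytes (3 of 14, Pf4 at 541 TPM) had too few expressed members for a test. Mitochondrially encoded transcripts (13 genes) are not in the table. Between replicates, reads of a gene varied 2.01 to 17.6 times as much as counting alone gives (chi-square per gene), most between ANR-1 and ANR-4.

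Hairpin sh2865 lowered Prdx3, whose protein removes peroxide from mitochondria, and sh1252 raised Mgst1 and Hp, a transferase and the haptoglobin gene. Such changes with a single hairpin raise the question of silencing through the seed, the short 5′ part of a small RNA that pairs with the 3′ UTRs of unintended transcripts. Tests of a seed of sh2865 or sh1252 and of length or composition were chosen only after the result was seen, and the predictions of the other tests were set down after the heptamers had been found but before the results of those tests.

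Genes with GCACATA in the 3′ UTR fell with sh2865 (z = -15.3, rank 1 of 16187 heptamers, 851 of 10276 genes, median log2 fold change -0.07 against 0.001 in the others). GCACATA lies at position 2882 of the Alox8 transcript, 17 nt after the number in the hairpin's name (GRCm38 chromosome 11: 69184270 to 69184276, 3′ UTR of exon 14), so silencing through the seed of sh2865 is a candidate explanation. For sh1252 the lowest heptamer was ACATCAA (z = -5.42, shuffled values up to 4.93), at positions 1269 (17 nt after its number, coding part of exon 9) and 555, and by fold changes it had rank 3 (z = -4.18) and the overlapping CACATCA, at 1268 and once more, rank 2 (z = -4.70), so a seed of sh1252 is a weaker candidate. Length or composition of the 3′ UTR is argued against, as 406 heptamers with the bases of GCACATA but no 5 in a row in common had a median z of -0.194 (95% from -2.26 to 1.68), or 0.182 against -14.7 for GCACATA without adjustment. Whether more sites go with more silencing stays open (2 or more sites against 1: -0.036, permutation test, two-sided, p = 0.171).

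Genes with CTTATCT rose with both hairpins (z = 7.65) but hardly differed between them (z = 1.19), which is consistent with silencing through the seed of the control hairpin in shRen. A biological effect of lost 15-LOX-2 on these genes was not tested apart from such silencing.

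Direct silencing by these seeds is argued against as the whole cause of the shared changes: 33.6% of 592 searched shared genes (95% exact interval 29.8% to 37.6%) had a heptamer that goes with their direction, fewer than 50%. These were 29.6% of the shared rises and 39.0% of the shared falls, against 14.3% and 27.9% of genes not called, an excess that the choice of the heptamers from these data partly fixes. Heptamers of both hairpins, which direct silencing of a shared fall by each would need, were in 9.45% of the falls (against 5.17%), which would make the share 20.9%, and AGCACAT counted for sh2865 would make it 36.3%. What moved the shared genes, such as indirect seed effects, stays open. Alox8 had 0 reads in all 4 shRen libraries, which argues against loss of its transcript as a cause. All groups were infected.

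For both hairpins, 1 of 100 splits of the libraries, the real one, reached 2209 (highest other 210), and for shared genes 616 (highest other 1). For sh1252, 1 of 35 reached 3254 (highest other 979), and for sh2865, 1 of 35 reached 1658 (highest other 112). These 4 counts argue against chance assignment only if libraries are independent, which no label says. Other splits mix the groups, adding spread. Between hairpins the 10 splits are too few for a share under 0.05 (1 of 10 reached 3250, highest other 2).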
